A study of Mus musculus with 12 samples.

How the data were processed

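The samples were cardiac myocytes freshly isolated from 2-week-old mice, 6 WT controls and 6 KO mice with a Myh6-Cre transgene and floxed Lmna, and each library came from a separate mouse according to the series design text. Per the labels' protocols, total RNA with an integrity number above 8 was depleted of ribosomal RNA, made into strand-specific libraries and sequenced as paired-end reads of 100 bases. The authors deposited 1 table of whole-number counts per gene for the 12 libraries, not normalized. The submitters' processing notes name Trim Galore for trimming, HISAT2 for alignment, featureCounts for counting and the GRCm38 build. The versions, the annotation, the strand setting and whether reads or pairs were counted are not given in the sources used here.

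The table held 21949 genes, all marked as protein coding in the table, of which 4052 had no count in any library. Genes of the mitochondrial genome were listed at 0 throughout and Xist was not among the genes. Gene positions, strands, lengths and GC content came from GENCODE M21 on GRCm38, where 21935 of the gene IDs (99.9%) were found and 96.6% carried the same version. Counts summed to between 10389220 and 14800378 in WT and between 12170713 and 15808951 in KO. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom from 8.24 to 51.7), so each library was counted as 1 replicate. Samples were grouped by their titles, and no column of the table was left without a sample.

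Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13015, and libraries were scaled by TMM factors. Each gene was tested with edgeR's quasi-likelihood F test with robust dispersion (glmQLFit and glmQLFTest, genotype only, two-sided). Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. CPM values are counts scaled by library total and TMM factor, means are given with SD over libraries, log2 fold changes with the model's SE, and folds are those of the model. The rule for named genes took Lmna, Brd4, and the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a predicted or clone name. Genes that passed these criteria numbered 293 higher and 600 lower. It also took up to 4 members per list: the 3 called members with the smallest p, the called member with the smallest p in the minority direction, or, where none was called, the 2 members with the highest CPM. Of 87 named genes 18 overlap another protein-coding gene, 17 of them only on the opposite strand, and are uncertain for that reason: Bex1, Synm, Csf1r, Cyfip2, Banf1, Polk, Ccl2, Fbn1, Tnni3, Myom1, Pfkm, Slc7a5, Shmt2, Fosl1, Dusp1, Brd2, Mb and Myl2. The globin genes Hba-a1 and Hbb-bs, like Lyz2, can share reads with near-identical copies.

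The groups, the test, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined. The 17 pathway lists covered the nuclear lamina and envelope, p53 targets, cell cycle and E2F targets, NF-kappa-B and inflammatory mediators, interferon response, extracellular matrix and TGF-beta, cardiac stress and fetal genes, sarcomere and Z-disc, ion channels with connexins and calcium handling, nuclear and mitochondrially encoded oxidative phosphorylation, fatty acid oxidation, glycolysis, integrated stress response, immediate-early and MAPK feedback genes, FOXO-linked genes, and BET proteins with P-TEFb. The 11 marker lists covered ventricular and atrial myocytes, fibroblasts, endothelial cells, macrophages, neutrophils, lymphocytes, smooth muscle and pericytes, epicardial or mesothelial cells, erythroid cells, and Schwann or neuronal cells. Lists with at least 5 tested members were tested with limma's camera on voom log2 CPM at a preset correlation of 0.01, adjusted within each kind of list. Camera with an estimated correlation and fry, which tests a common direction within a list, were alternatives. List scores are the mean log2 CPM of a list's tested members per library, and differences of scores were tested by exact permutation over all 924 splits, two-sided, with 10 scores adjusted together.

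The edgeR and camera steps were tested on simulated data for KO against WT with 6 libraries each and 13015 genes. Of 50 genes changed by each size, 52% were recovered at 1.5-fold, 80% at 2-fold, 96% at 3-fold and 94% at 4-fold, with a false share of 4.17% among the calls. Camera gave p below 0.05 for 3 of 100 random lists. The simulated genes were drawn independently, so this does not check camera on lists whose genes move together. Alternatives changed the size factors (relative log expression, upper quartile, library totals), the filter, the test (DESeq2, limma-voom with sample weights), the covariates (replicate numbers as a block, Y-linked reads, the first principal component of the residuals) and the libraries, each left out in turn. Because Xist was not among the genes, the covariate for sex used Y-linked genes alone. Chosen after seeing the data were a fit on the libraries with Y-linked reads (summed CPM above 50), a fit without KO 1 and KO 4, a fit on the 8 samples whose description numbers occur in both groups, and a fit with each library's trend over gene length and GC content removed. The alternative without mitochondrial genes moved nothing, since those genes had no counts. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.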

Results

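RNA was sequenced from cardiac myocytes freshly isolated from 2-week-old mice of 2 genotypes, with 6 mice in each group. In the KO mice, Cre recombinase made from the promoter of Myh6, the cardiac alpha myosin heavy chain gene, acts on floxed Lmna in cardiac myocytes. Lmna encodes lamins A and C, structural proteins of the nuclear lamina. The WT mice are controls, marked NTG in their sample descriptions, which may stand for non-transgenic. The labels do not otherwise say whether they carried the Cre transgene. Every difference between KO and WT may therefore include an effect of Cre. The series title places the libraries in a study of BRD4, a BET bromodomain protein that binds acetylated chromatin, in lamin-deficient hearts, and the labels describe no inhibitor-treated library among these 12. The comparison asks which protein-coding genes differ in abundance between myocytes of these KO and WT mice. Counts on protein-coding genes summed to between 10389220 and 14800378 per WT library and between 12170713 and 15808951 per KO library.

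Lmna itself was far lower in the KO libraries. It averaged 199 ± 5.2 CPM in WT and 69.5 ± 13.7 CPM in KO (SD, n = 6 each), a fall of 2.87-fold, to 34.9% of the WT mean. The WT libraries held 199, 195, 209, 196, 200.1 and 197 CPM in replicates 1 to 6, and the KO libraries held 72.6, 61.6, 93.6, 55.8, 60.5 and 72.9 CPM. Every KO library therefore lay below every WT library (log2 fold change −1.52 ± 0.11 SE, edgeR adjusted p = 1.1e-06). Lmna (ENSMUSG00000028063.15) lies on the minus strand of chromosome 3, from 88480147 to 88509956 in GRCm38, and its annotated exons cover 5838 bases. The counts cover the whole gene, and the labels do not name the floxed exons, so reads from exons outside the deleted part count towards the KO values.

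**Figure D1:**
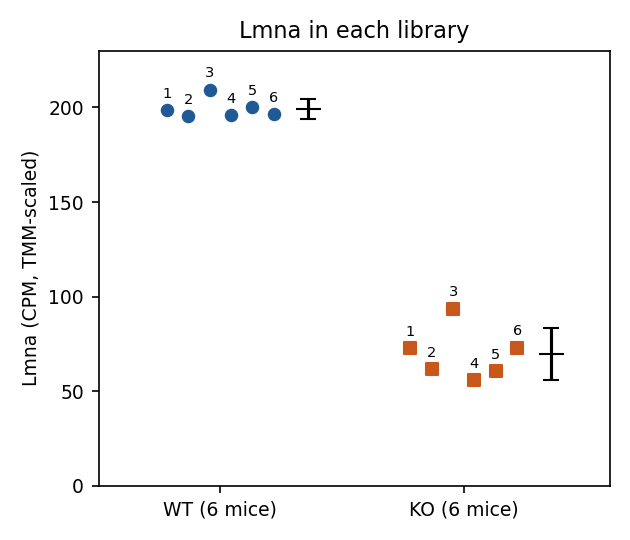
Lmna in TMM-scaled CPM (vertical axis) for each of the 6 WT (circles) and 6 KO libraries (squares), with replicate numbers above the points and bars for the mean ± SD. WT libraries lie between 195 and 209 CPM and KO libraries between 55.8 and 93.6 CPM.

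Lmna included, 1074 genes were higher and 1512 lower in KO among 13015 tested (edgeR adjusted p below 0.05). Many genes of energy metabolism, contraction and cardiac ion channels fell, while matrix, fibroblast and macrophage genes rose. The rises reached further: 213 genes rose at least 2-fold and 41 fell as far, while the median change was 1.46-fold among the genes that rose and 1.37-fold among those that fell. Libraries of the groups did not overlap for 1006 of the 13015 tested genes, where chance gives 0.216% of genes. Among called genes they did not overlap for 357 of the higher and 612 of the lower genes. Higher genes made up 41.5% of the calls with TMM scaling, 84.9% with library totals alone (3686 higher, 655 lower) and 55.7% with upper-quartile factors. Library totals alone raised the median of all genes by 0.21 on the log2 scale. KO libraries also had more genes detected (15524 to 16240, against 14338 to 15213 in WT) and higher TMM factors (1.02 to 1.16, against 0.871 to 0.961). The number of higher genes was 643 without KO 3 and 708 without KO 6, and 1026 without WT 6. With only the 8 libraries that had reads on Y-linked genes (3 WT, 5 KO) it was 146, with 215 lower.

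The 12 largest rises among called genes of at least 5 CPM whose groups did not overlap joined cell surface, stress and structural genes. Cd24a, a small surface glycoprotein on chromosome 10 (43578284 to 43584265), rose from 4.61 ± 1.97 to 24.1 ± 11.98 CPM (SD, n = 6 each). Lyz2, the lysozyme of macrophages, rose 5.11-fold, and Csf1r, the receptor for macrophage colony-stimulating factor, rose 2.79-fold. Hmox1, the haem-degrading heme oxygenase 1, rose from 6.12 ± 0.865 to 21.3 ± 9.89 CPM. Aldh1a2, which makes retinoic acid, rose 3.41-fold, and the matrix glycoprotein Tnc rose 2.92-fold. Synm, the intermediate filament protein synemin, rose 3.24-fold and Nmrk2, a nicotinamide riboside kinase of muscle, rose from 27.9 ± 6.95 to 78.2 ± 23.9 CPM. Bex1 rose 4.45-fold, Gcnt1, a glycosyltransferase, 4.2-fold, and both Ndnf and the sodium/calcium exchanger Slc24a2 rose 3.17-fold. The edgeR adjusted p of these genes ran from 0.000982 for Ndnf to 0.0146 for Tnc. Lyz2 can share reads with its close paralog Lyz1, and Bex1, Synm and Csf1r overlap genes on the opposite strand, whose reads are split from theirs only if the counting used strand.

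The 12 largest falls by the same rule were smaller and, beside Lmna, included muscle genes and a pair of neighbours on chromosome 16. Lrrc15 fell from 77.9 ± 11.6 to 27.6 ± 12.9 CPM (SD, n = 6 each), and Cpn2, 1.80 kb away on the same strand of chromosome 16, fell from 11.5 ± 2.73 to 4.94 ± 1.99 CPM. Ttll1, a tubulin polyglutamylase subunit, fell 2.55-fold, Extl1, an exostosin-like glycosyltransferase, 2.46-fold, and Smco1 2.48-fold. Rpl3l, the striated-muscle form of ribosomal protein L3, fell from 76.6 ± 19.9 to 34.3 ± 7.51 CPM. Lrrc10, a cardiac leucine-rich repeat protein, fell 2.35-fold, Tmem82 2.37-fold and Frmd5 2.23-fold. These 9 genes had edgeR adjusted p from 0.000200 for Extl1 to 0.0125 for Lrrc10. Pttg1, the securin of mitosis, fell 2.87-fold (adjusted p = 0.0335), and its call ended without any 1 of WT 4, WT 6, KO 1 and KO 3 (adjusted p up to 0.0780). Cyfip2, an actin regulator that overlaps a gene on the opposite strand, fell 2.19-fold (adjusted p = 0.0400), and its call ended without any 1 of WT 3 to 6, KO 1, KO 3 and KO 6 (adjusted p up to 0.0937).

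**Figure D2:**
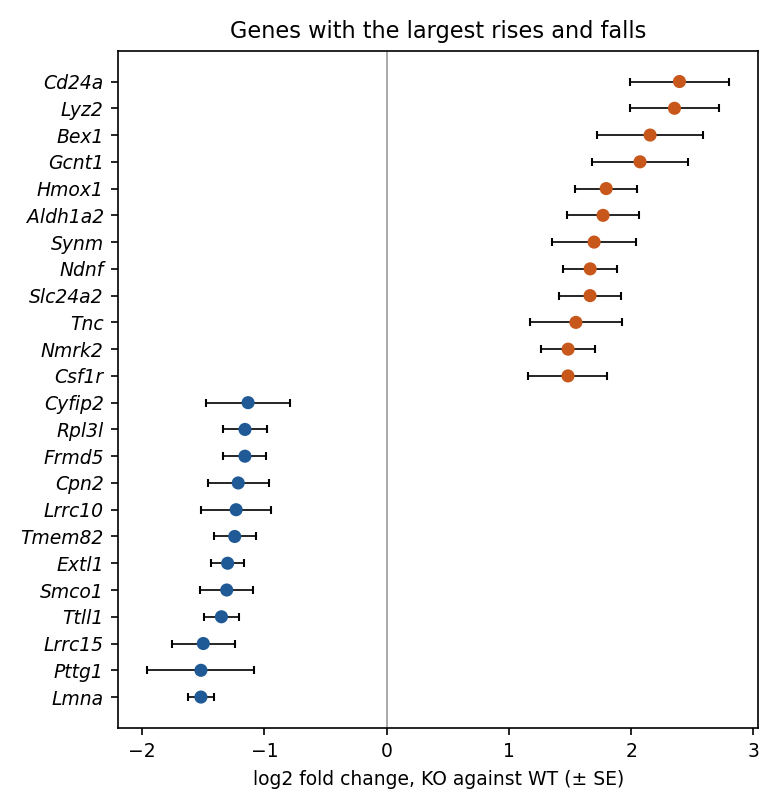
Log2 fold change of KO against WT (horizontal axis) with its standard error (bars) for the 12 genes that rose most and the 12 that fell most under the rule for named genes, from 6 libraries per group. Rises reach 2.39 for Cd24a, and falls reach −1.52 for Lmna and Pttg1.

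Genes of mitochondrial energy production fell together. Of 52 tested nuclear genes of oxidative phosphorylation, 48 fell, none rose and 4 did not pass the test, with a median log2 fold change of −0.48 (49 fell when adjusted over the list alone). Uqcrq, a subunit of complex III, fell from 323 ± 31.9 to 198 ± 32.2 CPM (SD, n = 6 each). Atp5g3, which makes the c ring of ATP synthase, fell from 1185 ± 94.6 to 736 ± 137 CPM, and the complex I subunit Ndufb3 fell 1.42-fold. Of 30 fatty acid oxidation genes 22 fell and none rose, with a median of −0.49 (23 fell when adjusted over the list alone). The dehydrogenase Hadh fell from 673 ± 69.98 to 361 ± 76.7 CPM, and each KO library lay below each WT library in this gene. Cpt2, the inner carnitine palmitoyltransferase of mitochondria, fell 1.6-fold and Etfa, an electron transfer flavoprotein subunit, fell 1.43-fold. The edgeR adjusted p of these 6 genes ran from 0.000960 to 0.00247. Camera, which sets a list against all other genes, gave adjusted p = 2.36e-27 and 6.10e-13, and for both lists adjusted p = 0.240 with an estimated correlation. Over all lists, camera called 11 of 16 tested pathway lists and 3 of 8 tested marker lists, and none of either with an estimated correlation; 16 and 58 of 100 splits of the libraries called as many. With only the libraries that had Y-linked reads, 3 oxidative phosphorylation and 4 fatty acid oxidation genes were among the 215 genes called lower. In 5 of 6 KO libraries the mean log2 CPM of the oxidative phosphorylation list lay below that of every WT library. The 13 genes of the mitochondrial genome are listed at 0 in every library and were not tested.

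Contractile and ion channel genes fell as well. Of 22 sarcomere and Z-disc genes 15 fell and none rose, with a median log2 fold change of −0.47 (16 fell when adjusted over the list alone). Tnni3, cardiac troponin I, whose gene overlaps another on the same strand, fell from 4722 ± 593 to 2713 ± 601 CPM (SD, n = 6 each). The M-band protein Myom1 fell 1.66-fold and the Z-disc protein Ldb3 1.52-fold. Of 30 genes for ion channels, connexins and calcium handling 14 fell and none rose, with a median of −0.43; adjusted over the list alone, 17 fell and 1 rose. Scn5a, the cardiac sodium channel, fell from 719 ± 209 to 383 ± 64.3 CPM. Hcn2, a pacemaker channel, fell 1.91-fold and Kcnj11, the pore of the ATP-sensitive potassium channel, fell 1.82-fold. The edgeR adjusted p of these 6 genes ran from 0.00135 to 0.00263. Camera gave adjusted p = 1.11e-09 for the sarcomere list and 1.79e-07 for the channel list, and for both adjusted p = 0.240 with an estimated correlation. With only the libraries that had Y-linked reads, 2 sarcomere and 4 channel genes were among the 215 genes called lower.

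All 10 ventricular myocyte markers fell, 8 of which also stand in other lists. The light chain Myl2 fell from 6562 ± 593 to 4339 ± 848 CPM and myoglobin, Mb, from 5293 ± 642 to 3567 ± 518 CPM (SD, n = 6 each), with edgeR adjusted p = 0.00607 and 0.00484. The median of the markers was −0.53 on the log2 scale, and all 10 also fell when adjusted over the list alone. With library totals alone 6 were called, and 0 with only the libraries that had Y-linked reads, where 215 genes in all were called lower. For this list camera gave adjusted p = 5.94e-07, and adjusted p = 0.343 with an estimated correlation. The mean log2 CPM of these markers was 12.49 ± 0.10 in WT and 11.93 ± 0.27 in KO (exact permutation p = 0.00216, the smallest the design allows, two-sided; adjusted p = 0.00722 over 10 scores). The mean of oxidative phosphorylation genes minus that of ventricular markers was 0.07 higher in KO (exact permutation p = 0.219). In the same KO libraries the markers of fibroblasts and macrophages were higher.

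**Figure D3:**
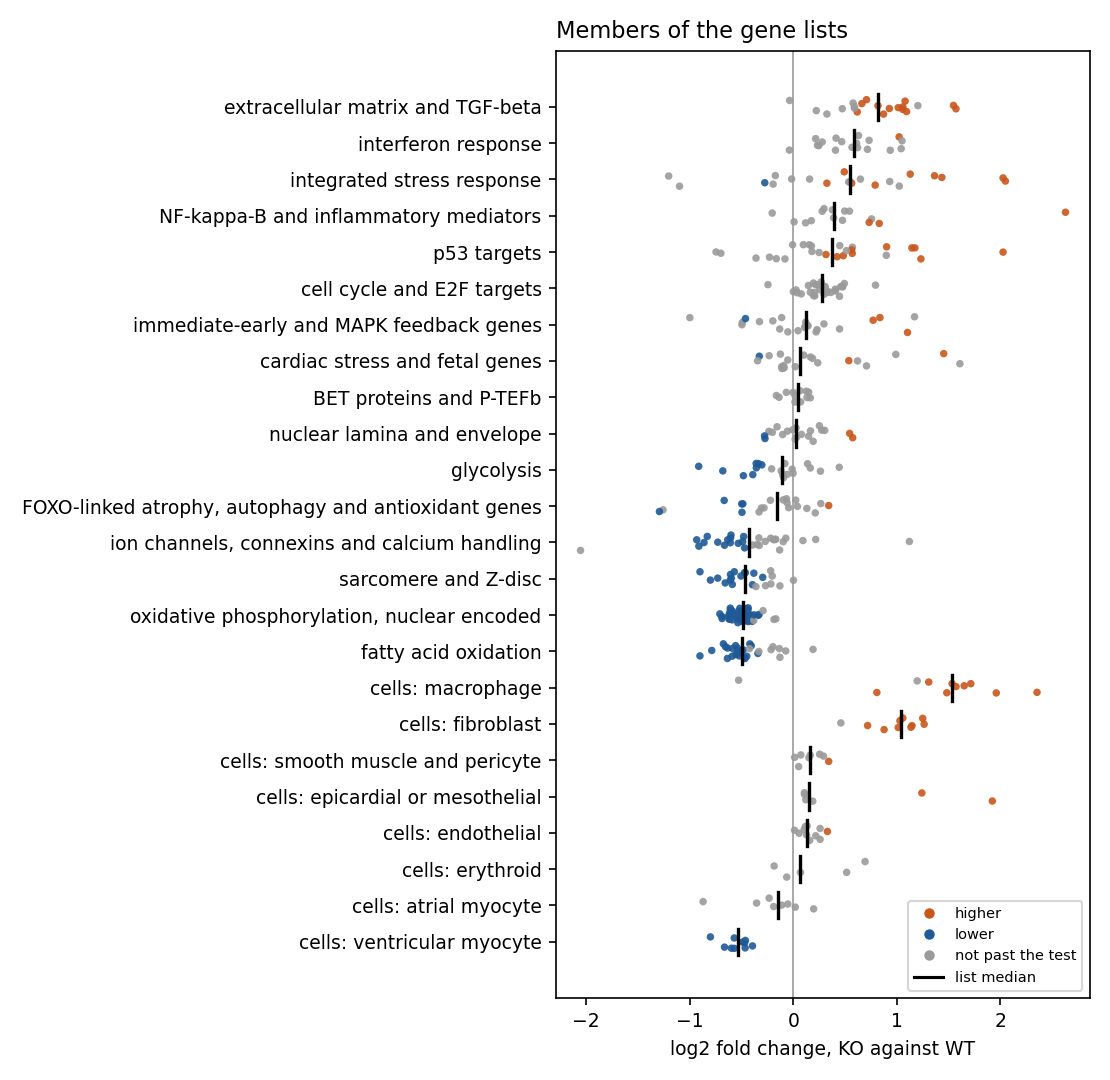
Log2 fold change of KO against WT (horizontal axis) of each tested member of the gene lists with at least 5 tested members; colours give genes called higher, called lower or not past the test at an edgeR adjusted p of 0.05, and black bars give list medians. The energy, sarcomere and ion channel lists lie left of 0, and the matrix, fibroblast and macrophage lists lie right of it.

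Matrix and fibroblast genes rose. Of 21 tested genes for extracellular matrix and TGF-beta 13 rose and none fell, with a median log2 fold change of 0.82 (17 rose when adjusted over the list alone). Collagen III, Col3a1, rose from 488 ± 31.6 to 1043 ± 437 CPM (SD, n = 6 each) and periostin, Postn, a matricellular protein, from 86.0 ± 16.6 to 179 ± 71.0 CPM. Fbn1, the microfibril protein fibrillin 1, rose 1.63-fold. Of 10 fibroblast markers 9 rose, with a median of 1.04 (9 when adjusted over the list alone). Only 5 were called without WT 3 or without WT 4, and 6 without any 1 of WT 1, WT 2, WT 5, KO 2 and KO 3. The proteoglycan Dcn rose from 71.1 ± 16.0 to 169 ± 77.2 CPM, Col1a2 rose 2.02-fold and Dpt 2.04-fold. The edgeR adjusted p of these 6 genes ran from 0.00284 to 0.00918. KO 3 held the highest values of Col3a1 (1901 CPM), Postn (314 CPM) and Col1a2 (765 CPM), and without it the matrix list had a median of 0.60 and all 13 genes stayed called. With only the libraries that had Y-linked reads, 6 matrix genes and 4 fibroblast markers were among the 146 genes called higher. Camera gave adjusted p = 1.79e-07 for the matrix list and 1.02e-05 for the fibroblast markers, and adjusted p = 0.240 and 0.343 with an estimated correlation. The mean log2 CPM of fibroblast markers was 4.80 ± 0.31 in WT and 5.73 ± 0.52 in KO (exact permutation p = 0.00649, two-sided, adjusted p = 0.0130).

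Macrophage genes rose from low levels. Of 11 tested macrophage markers 9 rose and none fell, with a median log2 fold change of 1.53 (10 rose when adjusted over the list alone). With only the libraries that had Y-linked reads 1 was called, where 146 genes in all were called higher. Besides Lyz2 and Csf1r, Cd14, the co-receptor for lipopolysaccharide, rose from 1.01 ± 0.549 to 3.87 ± 1.6 CPM (SD, n = 6 each; edgeR adjusted p = 0.00356). For these markers camera gave adjusted p = 0.000192, and adjusted p = 0.343 with an estimated correlation. The mean log2 CPM of the markers was 1.06 ± 0.27 in WT and 2.29 ± 0.64 in KO (exact permutation p = 0.00216, two-sided, adjusted p = 0.00722).

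Few markers of other cell types passed the test. Of 11 endothelial markers only the VEGF receptor gene Kdr rose, from 331 ± 35.6 to 416 ± 61.0 CPM (SD, n = 6 each; edgeR adjusted p = 0.0404). The list had a median log2 fold change of 0.13 (0.20 without WT 3 and 0.08 without WT 4), camera adjusted p = 0.0782 and no call when adjusted over the list alone. Camera called it without WT 3 (adjusted p = 0.0189), WT 6 (0.0106) or KO 5 (0.0138), with voom weights (0.0257), with the Y-linked covariate (0.00805), with only the libraries that had Y-linked reads (0.00394) and with library totals alone (0.0284), where 8 markers were called higher. Of 8 smooth muscle and pericyte markers only Rgs5 rose, 1.27-fold (adjusted p = 0.0424; camera adjusted p = 0.190; none when adjusted over the list alone); 5 were called higher with library totals alone, 2 with upper-quartile factors and 0 with relative log expression factors. The call of Kdr ended without any 1 of 8 libraries (WT 2, 4, 5 and 6, KO 1, 2, 3 and 6; adjusted p up to 0.0976). That of Rgs5 ended without any 1 of WT 1, 2, 4 and 5 and KO 1, 3, 4 and 6 (adjusted p up to 0.0991). Of 6 epicardial or mesothelial markers the keratins Krt8 (0.877 ± 0.828 to 3.19 ± 1.68 CPM) and Krt19 (1.65 ± 0.751 to 3.87 ± 1.87 CPM) rose, also when adjusted over the list alone (edgeR adjusted p = 0.0211 and 0.0239; camera adjusted p = 0.190). The call of Krt8 ended without WT 4 or KO 3 (adjusted p up to 0.0576), and that of Krt19 without any 1 of WT 3, WT 4, KO 1 and KO 3 (adjusted p up to 0.0672). None of 8 atrial markers passed the test, also when adjusted over the list alone: Myl7 held 314 ± 164 CPM in WT and 318 ± 348 CPM in KO, and Myl4 231 ± 124 and 213 ± 191 CPM (camera adjusted p = 0.190, and 0.0364 without KO 2). KO 1 and KO 4 were far below the other libraries in these genes, with Myl7 at 23.9 and 18.0 CPM, against 241 to 962 CPM in the other KO libraries and 122 to 538 CPM in WT. Camera also called the atrial list with library totals alone (adjusted p = 0.0148). Its median of −0.15 was 0.08 without WT 4 and 0.09 without KO 1, so its direction is unsettled. None of 5 erythroid or 3 Schwann or neuronal markers passed either with edgeR; the atrial, erythroid and Schwann or neuronal lists held 0 genes at an unadjusted p below 0.05, and DESeq2 called 0, 0 and 1. The erythroid list had a median of 0.07 and a mean of 0.21 while camera placed it below other genes (adjusted p = 0.895). Without KO 2 the median was −0.54 and the mean −0.32, and the median was −0.07 without WT 4 and −0.06 without WT 6, so the list gives no direction. Hbb-bs held 21.3 ± 11.4 and 20.4 ± 19.4 CPM, Hba-a1 15.2 ± 6.87 and 13.3 ± 10.9 CPM, Plp1 2.75 ± 1.31 and 2.26 ± 1.01 CPM, and Sox10 0.945 ± 0.516 and 1.497 ± 0.425 CPM. No neutrophil or lymphocyte marker had enough counts to be tested.

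**Figure D4:**
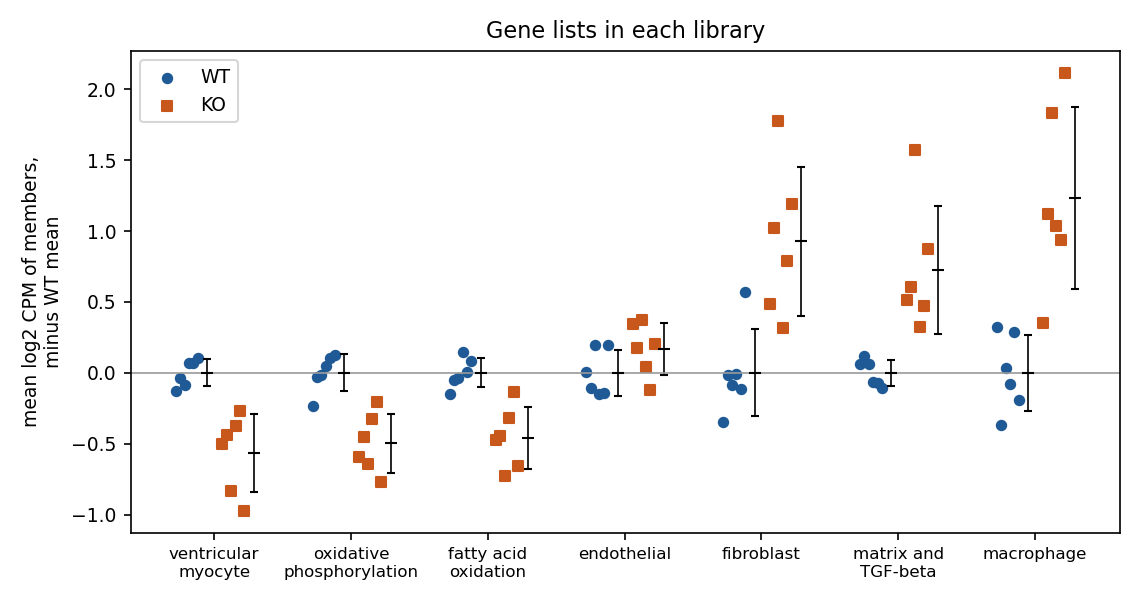
Mean log2 CPM of the members of 7 gene lists in each library, minus the mean of the WT libraries (vertical axis), for 6 WT (circles) and 6 KO libraries (squares), with bars for the mean ± SD. All 6 KO libraries lie below every WT library for ventricular markers and above every WT library for matrix and macrophage genes, 5 lie below for oxidative phosphorylation and for fatty acid oxidation, and 4 lie above for fibroblast markers.

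Stress response genes rose in part. Of 26 p53 target genes 10 rose and none fell, with a median log2 fold change of 0.37; adjusted over the list alone, 11 rose and 1 fell. Eda2r, a receptor for ectodysplasin A2, rose from 9.10 ± 2.85 to 20.3 ± 5.01 CPM (SD, n = 6 each), Polk, a translesion DNA polymerase, rose 1.87-fold and the nuclease gene Aen 1.34-fold, each with every KO library above every WT library. Of 21 genes of the integrated stress response 9 rose and 1 fell, with a median of 0.55 (11 and 3 when adjusted over the list alone); without KO 3 only 3 were called higher. Psat1, of serine synthesis, rose from 5.64 ± 1.55 to 14.6 ± 2.96 CPM, the amino acid transporter Slc7a5 rose 1.73-fold and the secreted factor Gdf15, which the p53 list also holds, 4.07-fold. Shmt2, the mitochondrial serine hydroxymethyltransferase, fell 1.21-fold (edgeR adjusted p = 0.0248), a call that ended without any 1 of WT 3, WT 4, KO 2, KO 3 and KO 6 (adjusted p up to 0.0583) and with library totals alone. The edgeR adjusted p of the 6 genes that rose ran from 0.000951 to 0.0162. Camera gave adjusted p = 0.000900 for the p53 list and 0.00895 for the stress response, and adjusted p = 0.240 and 0.338 with an estimated correlation. With library totals alone the stress response list had camera adjusted p = 0.104. With only the libraries that had Y-linked reads 3 p53 targets and 2 stress response genes were among the 146 genes called higher.

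Inflammatory genes rose in small number. Of 15 tested NF-kappa-B and inflammatory genes 3 rose and none fell (7 rose when adjusted over the list alone), with a median log2 fold change of 0.39; 9 were called higher with library totals alone, 6 with upper-quartile factors, 6 without KO 5 and 5 without WT 5. The adhesion molecule Vcam1 rose from 10.6 ± 2.75 to 18.99 ± 3.58 CPM (SD, n = 6 each). The chemokine Ccl2, at 0.749 ± 0.610 CPM in WT, rose 6.18-fold, and Tnfaip3, a ubiquitin-editing inhibitor of NF-kappa-B, rose 1.66-fold (edgeR adjusted p from 0.00406 to 0.00802). Of 18 interferon response genes only Ifit2 rose, from 6.85 ± 2.70 to 13.9 ± 6.59 CPM (edgeR adjusted p = 0.0351), and none when adjusted over the list alone. Its call ended without any 1 of WT 1, 3, 4 and 5, KO 3 and KO 6 (adjusted p up to 0.0804). Camera gave adjusted p = 0.00143 for the inflammatory list and 0.00373 for the interferon list, and adjusted p = 0.240 and 0.547 with an estimated correlation. With library totals alone the interferon list had camera adjusted p = 0.104 and 7 genes called higher, and 4 were called with the Y-linked covariate. KO 3 and KO 6 had the highest mean log2 CPM of all 12 libraries for the inflammatory (4.02 and 3.98), interferon (4.51 and 4.16) and macrophage lists (2.89 and 3.18). All 6 KO libraries lay above every WT library for the inflammatory and macrophage lists, and only these 2 for the interferon list.

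Immediate-early, cardiac stress and fetal genes moved in both directions. Of 23 immediate-early and MAPK feedback genes 3 rose and 1 fell (3 and 1 when adjusted over the list alone; camera adjusted p = 0.598); 6 were called higher and 0 lower with library totals alone. Myc rose from 3.75 ± 0.978 to 6.73 ± 2.23 CPM and Fosl1, an AP-1 subunit, from 2.74 ± 0.578 to 4.69 ± 1.01 CPM, while Dusp1, a MAP kinase phosphatase, fell from 184 ± 34.9 to 134 ± 23.3 CPM (SD, n = 6 each; edgeR adjusted p = 0.0196, 0.0218 and 0.0250). Without KO 6 the adjusted p of Myc was 0.0583 and that of Fosl1 0.0615, and the call of Dusp1 ended without WT 6, KO 2 or KO 6 (adjusted p up to 0.0573) and with library totals alone. Of 20 cardiac stress and fetal genes 2 rose and 1 fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.598); here too 6 were called higher and 0 lower with library totals alone. The LIM protein gene Fhl1 rose from 120.3 ± 16.9 to 329 ± 192 CPM and Actn1, non-muscle alpha-actinin, 1.45-fold, while Csrp3, the muscle LIM protein of the Z-disc, fell 1.25-fold (edgeR adjusted p = 0.0135, 0.0103 and 0.0215). The call of Csrp3 ended without WT 5, KO 1 or KO 2 (adjusted p up to 0.0511) and with library totals alone.

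Glucose metabolism and FOXO-linked genes fell in part. Of 20 glycolysis genes 8 fell and none rose, also when adjusted over the list alone, with a median log2 fold change of −0.11 that was 0.10 with library totals alone, or −0.15 relative to all genes. With library totals alone 2 fell and 1 rose, without KO 3 4 fell, and 5 fell without any 1 of WT 4, WT 5, KO 1 and KO 6. Slc2a4, the insulin-responsive glucose transporter GLUT4, fell from 756 ± 178 to 401 ± 68.6 CPM (SD, n = 6 each), Pfkm, the muscle phosphofructokinase, 1.6-fold and Ldhb, a lactate dehydrogenase, 1.31-fold (edgeR adjusted p from 0.00173 to 0.0122); the call of Ldhb ended with library totals alone. Of 20 FOXO-linked genes 5 fell and 1 rose (6 and 1 when adjusted over the list alone), with a median of −0.16 that was 0.05 with library totals alone, or −0.20 relative to all genes; 3 were called lower with library totals alone, 2 without KO 3, and 3 without any 1 of WT 4, KO 1 and KO 2. Trim63, an E3 ligase of muscle atrophy, fell 1.40-fold, mitochondrial superoxide dismutase Sod2 1.41-fold and Klf15 2.45-fold, and Foxo1 rose 1.27-fold (edgeR adjusted p from 0.00558 to 0.0355). The adjusted p of Klf15 was 0.0552 without KO 3, and the call of Foxo1 ended without any 1 of 9 libraries (WT 2, 4, 5 and 6, KO 1, 2, 3, 4 and 6; adjusted p up to 0.0852). For glycolysis and the FOXO list camera gave adjusted p = 0.00344 and 0.0239, and adjusted p = 0.343 and 0.411 with an estimated correlation. The FOXO list was not called without WT 6 (median −0.09, adjusted p = 0.0796) or KO 1 (adjusted p = 0.0716).

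In the model with genotype alone, few genes of the nuclear envelope and none of the BET and cell cycle lists passed the test. Of 20 lamina and envelope genes 2 rose and 2 fell (3 and 2 when adjusted over the list alone; camera adjusted p = 0.730). Syne2, the outer membrane protein nesprin 2, rose from 145 ± 25.1 to 211 ± 34.2 CPM and Tmem43, an inner membrane protein, from 38.4 ± 5.68 to 57.2 ± 16.1 CPM, while the chromatin-binding factor Banf1 fell 1.21-fold (SD, n = 6 each; edgeR adjusted p = 0.00730, 0.0202 and 0.0227). The lower calls of this list numbered 0 without KO 3 and 1 without any 1 of WT 1, 2, 4, 5 and 6, KO 1, KO 2 and KO 6. The call of Banf1 ended without KO 3 or KO 6 (adjusted p up to 0.0576) and with library totals alone, where 8 genes of this list were called higher and 0 lower. Brd4 (ENSMUSG00000024002.17; chromosome 17, 32196274 to 32284722, minus strand) held 40.9 ± 7.10 CPM in WT and 44.9 ± 5.44 CPM in KO (log2 fold change 0.13 ± 0.11 SE, edgeR adjusted p = 0.423). None of 12 genes for BET proteins and P-TEFb, the kinase that BRD4 recruits, passed the test, also when adjusted over the list alone (camera adjusted p = 0.717), while 7 were called higher with library totals alone, which shift all genes upward. Brd2 held 205 ± 22.7 and 208 ± 14.01 CPM, and Med1 122 ± 8.09 and 109 ± 12.7 CPM. None of 30 cell cycle genes passed in this model, also when adjusted over the list alone (camera adjusted p = 0.239, and 0.0360 without WT 1, 0.0276 without WT 2, 0.0246 without KO 5 and 0.0214 without KO 6): the proliferation marker Mki67 held 40.2 ± 24.6 and 53.7 ± 34.8 CPM, and Pcna 48.8 ± 8.44 and 50.1 ± 7.56 CPM. With edgeR in this model 0 genes of the BET and cell cycle lists had an unadjusted p below 0.05, and DESeq2 called 0. A block on the replicate number changed the cell cycle result: 2 genes were called higher and camera adjusted p was 0.0133. A block on the description numbers changed it further, as given in the part on processing.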

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

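The tests of a lower myocyte share, of more fibroblast RNA, of the sex of the WT 6 animal and of depth for single genes of WT 6 were chosen only after the result was seen. In 100 splits of the 12 libraries into 6 and 6, the real one included, only 1 called as many genes higher (1074, against at most 68 in the others). Only 1 called as many lower (1512, against at most 68). This argues against chance for both counts, though 1 in 100 is the smallest share these splits allow. The other splits mix the genotypes within a group, which can lower their counts. Chance cannot be excluded for the number of camera calls: 16 of 100 splits called at least as many pathway lists (11 in the real split, at most 13 in the others) and 58 of 100 at least as many marker lists (3, against at most 7).

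The first pattern is the fall of contractile and energy genes in KO libraries. A lower share of myocyte RNA that raised all other cell types alike would move fibroblast and endothelial markers together. The rise of fibroblast markers exceeded that of endothelial markers by 0.76 on the log2 scale (exact permutation p = 0.0130, two-sided), which argues against such an even rise as the whole cause. The test cannot decide on a share lowered by added fibroblasts and macrophages, which need not raise endothelial markers. Oxidative phosphorylation genes minus ventricular markers were 0.07 higher in KO (exact permutation p = 0.219). A lower share would leave that difference unchanged only if the RNA of both lists came from myocytes alone, so it does not decide on the share. With each library's trend over gene length and GC content removed, the median of the oxidative phosphorylation list was −0.43 and 46 of 48 called genes stayed called. With library totals alone it was −0.28 and 39 stayed called, so TMM scaling accounts for part of the size at most. Lower expression within myocytes that lack lamin A/C remains a hypothesis. Whether part or all of the fall comes with added fibroblast and macrophage RNA stays open, as does an effect of Cre, which was not tested.

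The second pattern is the rise of matrix, fibroblast and macrophage genes. With the Y-linked covariate the median of the matrix list was 0.93, and without KO 3 it was 0.60. All 13 called genes were called in each fit. For the matrix list this argues against a sex imbalance and against 1 extreme library as the whole cause. With only the libraries that had Y-linked reads, fewer matrix genes were called, among 146 genes called higher against 1074 in the main fit. That fit also held fewer libraries, so it does not decide on a part played by sex. More fibroblast RNA in KO libraries cannot be told apart from a change within cells: matrix genes outside the marker list rose by 0.23 less than fibroblast markers (difference −0.23, 95% interval −0.68 to 0.22), and the interval includes 0 and also reaches beyond 0.47 in size, which is 0.5 of the fibroblast rise. Macrophage markers rose by more than endothelial markers (difference 1.06, exact permutation p = 0.00866). More macrophages in the tissue of KO mice or in the isolated cells may contribute, which these libraries do not separate.

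The third pattern is that WT 6 stood apart from the other WT libraries, with the lowest total (10389220 counts), the lowest second principal component (−42.5) and 6 of the 14 values listed next. Thinning every library to its total left its cell cycle score about as far from the others (gap over range 0.570, and 0.569 before, below the critical value used here), so that score does not decide on depth. All 5 genes that were far apart in WT 6 stayed so after thinning, so the greater depth of the other libraries does not account for their gaps. Thinning leaves WT 6 itself unchanged, so it does not test sampling noise in the values of that library. WT 2 and WT 3 also lacked Y-linked reads, and WT 6 lay −3.89 SD from their mean cell cycle score, which argues against sex alone. No other biological explanation was tested, because the labels give no further property of this mouse than its numbers. KO 6 carries the same replicate and description numbers and had the lowest second principal component among KO libraries (−32.0). WT 6 and KO 6 also correlated best with each other in their deviations from the group means (r = 0.27). Something shared by these libraries was not tested.

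A value far from the others of its group, with a gap to the nearest, as a share of the group's range, above Dixon's 95% critical value, was found in 14 of 228 groups of values, where chance gives about 1 in 20, or 11.4. In WT 6, Lrrc10 was at 459.9 CPM (134 to 235 in the other WT libraries), Scn5a at 1130.5 CPM (538 to 695), Dpt at 21.7 CPM (12.1 to 14.8), Dcn at 102 CPM (55.8 to 67.8), Postn at 54.3 CPM (85.2 to 100.3) and the fibroblast list at a mean log2 CPM of 5.37 (4.45 to 4.79). In KO 3, Tnc was at 45.7 CPM (10.6 to 20.6 in the other KO libraries), Col3a1 at 1901 CPM (671 to 1038), Postn at 314 CPM (113 to 180.2) and Col1a2 at 765 CPM (258 to 420.4). Hadh was at 505 CPM in KO 5 (299 to 375), and Myc at 11.2 CPM in KO 6 (5.12 to 6.57). Lmna was at 209 CPM in WT 3 (195 to 200.1) and Brd4 at 54.7 CPM in WT 1 (36.3 to 42.4).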

How the results depend on the processing

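The fits on libraries with Y-linked reads, without KO 1 and KO 4, on 8 samples without a block and with the length and GC trend removed, like the rule that a sign change between uncalled values (44 cases, 4 of them beyond their spread) is no reversal, were chosen only after the result was seen. Of 76 called named genes 33 kept their call under all 27 alternatives, 18 lost it only in the fit on libraries with Y-linked reads, 15 lost it without at least 1 library, and none changed direction. Library totals alone gave 3686 genes higher and 655 lower, of which 1074 and 655 were also called with TMM, 5 marker lists, and opposite signs for the means of the glycolysis list (0.0325) and the atrial list (0.0266); this follows from the shift of all genes by 0.21. The 8 samples without a block gave 461 and 959. The libraries with Y-linked reads (3 WT, 5 KO) gave 146 and 215 (123 and 206 shared) with 5 marker lists. Fewer samples entered these fits than the main one. Both held 8 libraries, so their number alone does not account for the smaller counts of the second, whose cause was not tested. Camera with an estimated correlation called 0 pathway and 0 marker lists, and fry called 9 and 3, without the interferon (adjusted p = 0.169) and FOXO (0.107) lists. Leaving out 1 library gave from 643 (KO 3) to 1196 (WT 1) genes higher, 708 without KO 6, from 1082 (KO 3) to 1723 (KO 5) lower, from 10 to 12 pathway lists, from 3 to 4 marker lists and Lmna from −1.62 to −1.46. Other counts lay within 1.5 times: DESeq2 gave 1336 and 1793, voom 1196 and 1581, relative log expression 991 and 1595, no filter 1122 and 1422, the Y-linked covariate 1080 and 1410, no KO 1 and KO 4 769 and 1203. The endothelial list was called with voom weights (adjusted p = 0.0257) and the Y-linked covariate (0.00805); the cause was not tested.

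The replicate number as a block gave 1410 genes higher and 1763 lower, and camera then also called the cell cycle (adjusted p = 0.0133, 2 genes higher) and endothelial (0.0182) lists. The labels do not say what a shared number means. Deviations of same-numbered libraries had correlations from 0.0095 to 0.34, against a mean of −0.029 for other pairs of a WT and a KO library. Correlations were above 0.1 in 3 of 6 pairs (3 of the 4 that also share the description number). Of 12 libraries 7 correlated best with their own number. The number may therefore mark something shared, which the model with genotype alone ignores. The numbers in the descriptions as a block, on 8 samples, gave 1000 and 1496, with 5 marker lists, and called 15 of 30 cell cycle genes higher (median log2 fold change 0.62, camera adjusted p = 6.7e-08); on the same samples without the block 0 were called (median 0.49, camera adjusted p = 0.00552), with 0 fibroblast markers called against 4 with it. The cause was not tested. At this depth, 1.5-fold changes were recovered in 52% of simulated genes, so smaller changes can be missed. Far fewer genes changed in the simulation than were called in the real data, so the real share may differ.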

Other observations

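The tests of gene families, of genes near Lmna and of single genes named here were chosen only after the result was seen. Fisher's test counts genes as independent, though genes of a family can move together. For the oxidative phosphorylation list the estimated correlation was 0.82, and camera with it gave adjusted p = 0.240. Fisher's p-values below therefore do not measure variation between mice. Many genes of mitochondrial groups beyond the fixed lists fell too. Of 77 tested genes for mitochondrial ribosomal proteins (Mrpl, Mrps) 51 fell and none rose (66.2%, against 11.3% of other genes; odds ratio 15.4, Fisher's exact p = 1.1e-29, adjusted p = 1.1e-28 over 10 tests), with a median log2 fold change of −0.37, or −0.17 with library totals alone, where 25 fell and 2 rose; relative to all genes these medians were −0.41 and −0.42. Mrpl34 fell from 210.0 ± 32.8 to 114.5 ± 12.8 CPM (SD, n = 6 each; edgeR adjusted p = 0.000674). Of 22 genes for mitochondrial protein import (Timm, Tomm) 13 fell (Fisher's exact test, adjusted p = 6.0e-07), and of 16 Asb genes, which encode ankyrin repeat proteins with a SOCS box, 7 fell (adjusted p = 0.00311); with library totals alone 5 import genes fell and 1 rose, and 5 Asb genes fell and 2 rose. Asb14 fell 2.01-fold and Asb10 1.88-fold, and Mtln, which encodes a mitochondrial micropeptide, fell 1.86-fold. Of 37 proteasome subunit genes 12 fell (adjusted p = 0.00221), with a median of −0.16 that turned to 0.06 with library totals alone, where 2 fell and 2 rose; relative to all genes these medians were −0.20 and −0.19.

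Several genes of low abundance rose by more than any gene named by the rule. The interferon-inducible Ifi202b rose from 0.0677 ± 0.106 to 1.63 ± 0.739 CPM (SD, n = 6 each; edgeR adjusted p = 0.00124). The scavenger receptor gene Msr1 rose 11.1-fold, the NADPH oxidase subunit gene Cybb 6.80-fold and Gpnmb 8.34-fold (edgeR adjusted p from 0.00124 to 0.0257). Krt18, the keratin that pairs with Krt8, rose from 1.04 ± 0.884 to 7.36 ± 5.99 CPM (adjusted p = 0.00649). Cdkn1a, the p53 target p21, held 20.5 ± 15.1 CPM in WT and 37.8 ± 14.8 CPM in KO (adjusted p = 0.159, and 0.0133 without WT 6, which held 49.7 CPM).

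A hypothesis for the Lmna counts left in KO libraries is RNA of other cells, in which the Cre transgene is not active. Over the 6 KO libraries Lmna rose with the mean of the fibroblast and endothelial scores (Spearman's rho = 0.943, exact permutation p = 0.0167; Pearson's r = 0.892, exact permutation p = 0.0236; 1 relation was tested). Without the 2 libraries farthest from the median r was 0.37, so the relation rests on those libraries. It is consistent with such a source but does not exclude reads from exons outside the deleted part.

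Lamina-bound chromatin is gene-poor, so genes higher in KO were set against random genes matched on expression and length. They had a median of 20 protein-coding neighbours within 1 Mb, against 23 in matched lists (22 to 25; permutation p = 0.00040, adjusted p = 0.00080), which may reflect a tie to gene-poor regions or to the tissue-specific genes that lie there. Genes lower in KO had a median of 34, against 32 (31 to 34; permutation p = 0.165). Of genes within 5 Mb of Lmna 16.8% were called, against 19.9% elsewhere (Fisher's exact p = 0.468), which argues against strain DNA around the locus as a source of many calls. Among X-linked genes 12.3% were higher in KO, against 8.12% of autosomal genes (odds ratio 1.58, Fisher's exact p = 0.00366, adjusted p = 0.00966 over 6 tests), and 6.99% were lower, against 11.8% (odds ratio 0.56, Fisher's exact p = 0.00181, adjusted p = 0.00966). With the Y-linked covariate the odds ratio of higher genes was 1.57 (Fisher's exact p = 0.00483), which argues against a sex imbalance as the whole cause of that excess. The odds ratio of lower genes was then 0.66 (Fisher's exact test, adjusted p = 0.0292). With only the libraries that had Y-linked reads it was 0.28, on 2 X-linked genes (adjusted p = 0.0507). The odds ratio of higher genes was 2.49 in that fit (adjusted p = 0.0114). The shortage was no smaller there, but 2 genes are too few to decide on a part of a sex imbalance in it.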
